A study of Arabis alpina with 12 samples.

How the data were processed

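Messenger RNA was sequenced from leaves and shoot apices of Arabis alpina, a perennial relative of Arabidopsis, in the accession Pajares (wild type, WT) and in the pep1-1 mutant. Plants were 2 weeks old per the sample labels, while the series design text gives a younger age, and were grown at 22 °C in long days and harvested 8 h after lights on (ZT8). The labels give 3 replicates in each of the 4 groups, 12 libraries in all. Mutant libraries were taken from the genotype label; their titles read PEP1 in place of pep1-1, and every direction given here rests on that label. They do not say that replicates were separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, 4 µg of total RNA was purified for polyadenylated RNA, libraries were amplified over 12 PCR cycles with a TruSeq kit, and all libraries were pooled for sequencing.

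The deposited values are whole-number read counts per annotated transcript, made by the authors and not normalized. TopHat, bedtools and DESeq2 1.10.0 are named in the submitters' processing notes, which give no role for any of them. The aligner settings, genome build, annotation version and strand setting are not given in the sources used here, so coordinates are as the deposited tables give them. Without a stated strand setting, reads from overlapping or antisense genes cannot be assigned to one of them, and near-identical gene copies may share reads. The tables hold 39814 transcripts of 35465 genes on 8 chromosomes and 4046 scaffolds. Transcripts of one gene share reads, so 1 transcript was used for each gene, the one with most reads over the 12 libraries; 3593 genes had several. The other transcripts held between 4.90% and 5.65% of the counts in a library.

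The files do not pair gene identifiers with names. The targeted gene PEP1 was therefore not checked in these libraries, and the 15 gene lists fixed before the data were examined were not tested. Per comparison, at most 2 identifiers that rose and 2 that fell are printed, and other loci are given by position.

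Each comparison used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, the filterByExpr filter, robust dispersion and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p under 0.05. Leaf and apex libraries were fitted apart for the genotype comparisons, and all 12 libraries together for the genotype by tissue interaction and for apex against leaf in WT. Standard errors of log2 fold changes were approximated as the absolute fold change over the square root of F. CPM values are counts scaled to library size with the TMM factors, and SD is between replicates. In the genotype comparisons these factors were computed within each tissue, so those CPM values cannot be compared between leaf and apex. The tissue comparison used factors computed over all 12 libraries. Overlap of leaf and apex genes was tested with a one-sided Fisher's exact test over genes tested in both tissues, whose control libraries are separate.

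The comparisons, their tests and the rule for named genes were set before the data were examined. For a genotype comparison the rule took genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the replicates of the 2 genotypes, and ranked the 12 largest rises and the 12 largest falls. For the tissue comparison the minimum was a mean log2 CPM of 5. Of 3 against 3 libraries, 10% of random orders show no overlap.

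Alternatives were DESeq2 median-ratio factors, the DESeq2 1.42.0 Wald test, limma 3.58.1 with voom, no low-count filter, the replicate number as a block, all 12 libraries in one fit, stricter thresholds, and each library left out in turn. All transcripts, the first transcript of each gene, and genes without overlapping models were added after the data had been seen. The procedure was tested on simulated counts with known changes. Each simulated gene took the dispersion of the trend at its level, without further spread between genes. Many genes were changed at once, which eases the adjusted threshold, so recovery in the real genotype comparisons and interaction may be lower. In leaf it recovered 64.6% of 1.5-fold, 86.4% of 2-fold and 100% of 4-fold changes among 22914 genes, with 7 false calls. In apex it recovered 23.9%, 71.2% and 98.5% among 22132 genes, with 6 false calls. For the interaction it recovered 10.8%, 52.2% and 87.9% among 23494 genes, and for the tissues 53.7%, 86.4% and 95.5% among 23285 genes. The simulated tissues differed only in the changed genes, whereas 15300 genes passed in the real tissue comparison. These tissue values therefore say little about recovery there.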

Results

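Transcript levels were measured by RNA sequencing in leaves and shoot apices of WT and pep1-1 plants, with 3 libraries per genotype and tissue. PEP1 is the Arabis alpina orthologue of FLC, a transcription factor that represses flowering in Arabidopsis. Counted reads per library, with 1 transcript per gene, ranged from 21841331 to 38819193 in WT leaf, 22483197 to 36295150 in pep1-1 leaf, 19746210 to 33665939 in WT apex and 32022088 to 43695184 in pep1-1 apex. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom from 5.54 to 86.6, so no library was a copy of another. A single gene took 4.52% ± 0.230 (SD, n = 6) of the reads in apex and 0.973% ± 0.156 (SD, n = 6) in leaf (exact two-sided permutation p = 0.00216).

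The first question was which leaf transcripts differ between pep1-1 and WT. The gene Aa_G647150 on chromosome 6 (4449808 to 4451761) was almost silent in WT leaves, at 0.512 ± 0.521 CPM, and reached 42.8 ± 3.36 CPM in pep1-1 leaves (SD, n = 3 each). Aa_G633320 on chromosome 3 (24168695 to 24171270) rose from 1.09 ± 0.564 to 9.33 ± 0.417 CPM. In the opposite direction, Aa_G117060 on chromosome 6 (4661693 to 4663219) stood at 37.4 ± 16.1 CPM in WT and 0.293 ± 0.180 CPM in the mutant, and Aa_G365540 on chromosome 8 (5257134 to 5261576) fell from 7.01 ± 0.222 to 0.598 ± 0.181 CPM. The log2 fold changes of the 2 genes that rose were 6.64 (SE 0.36, edgeR adjusted p = 0.000807) and 3.19 (SE 0.27, edgeR adjusted p = 0.00232). Those of the 2 genes that fell were -6.90 (SE 0.49, edgeR adjusted p = 0.00262) and -3.54 (SE 0.20, edgeR adjusted p = 0.000172). The log2 fold change of Aa_G647150 was 7.63 without WT leaf replicate 2. None of these loci overlaps another gene model.

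Across the leaf transcriptome, 95 of 22936 genes passed the threshold, 57 higher and 38 lower in pep1-1. Of these, 64 changed at least 2-fold and 36 at least 4-fold. Among genes that met the rule, the 12 largest rises spanned log2 fold changes from 1.56 to 6.64. The rule's minimum level is a mean over both genotypes, so it can leave out genes nearly silent in one of them. A gene on scaff_47458_1 left out in this way had a log2 fold change of 6.88. At an unadjusted p under 0.05 there were 2233 genes, against 1146.8 expected by chance. Chromosome 2 carried 16 of the leaf genes where 8.14 were expected, and chromosome 7 carried 3 where 8.56 were expected. This uneven spread had a permutation p of 0.0116 (0.0233 after adjustment over the 2 tissues), and in 12 of 17 alternatives the p was above 0.05. The count of genes changed when single libraries were left out. It was 445 without WT leaf replicate 1, with all 95 genes kept, and 39 without WT leaf replicate 3. It was 39 without pep1-1 leaf replicate 1 and 40 without pep1-1 leaf replicate 2. These smaller counts held 38, 36 and 39 of the 95 genes. A fit with fewer libraries also has less power, so the falls need not rest on 1 library. The count was 322 with DESeq2 and 157 without the low-count filter.

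The same question was asked of the shoot apex. Aa_G647150 was again higher in the mutant, at 19.9 ± 2.103 CPM against 0.380 ± 0.398 CPM in WT (SD, n = 3 each). Aa_G263810 on chromosome 8 (26096563 to 26097447) rose from 0.416 ± 0.102 to 8.82 ± 1.01 CPM. Aa_G579940 on chromosome 8 (5765423 to 5770059) fell from 26.5 ± 1.55 to 3.84 ± 1.09 CPM, and Aa_G365540 fell from 6.23 ± 0.670 to 1.27 ± 0.467 CPM. The log2 fold changes of Aa_G647150 and Aa_G263810 were 5.57 (SE 0.41, edgeR adjusted p = 0.00194) and 4.38 (SE 0.21, edgeR adjusted p = 0.000161). Those of Aa_G579940 and Aa_G365540 were -2.78 (SE 0.19, edgeR adjusted p = 0.00142) and -2.32 (SE 0.25, edgeR adjusted p = 0.0148). The locus on chromosome 6 (4661693 to 4663219) that fell in leaf also fell in apex, from 28.2 ± 10.2 to 0.0970 ± 0.0947 CPM. Its log2 fold change was -8.00 (SE 0.51, edgeR adjusted p = 0.00103), but its mean log2 CPM of 0.92 was below the rule's minimum. The log2 fold change of Aa_G647150 in apex was 6.88 without WT apex replicate 1. For Aa_G365540 in apex the edgeR adjusted p was 0.0896 without WT apex replicate 1 and 0.0849 without WT apex replicate 2.

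**Figure D1:**
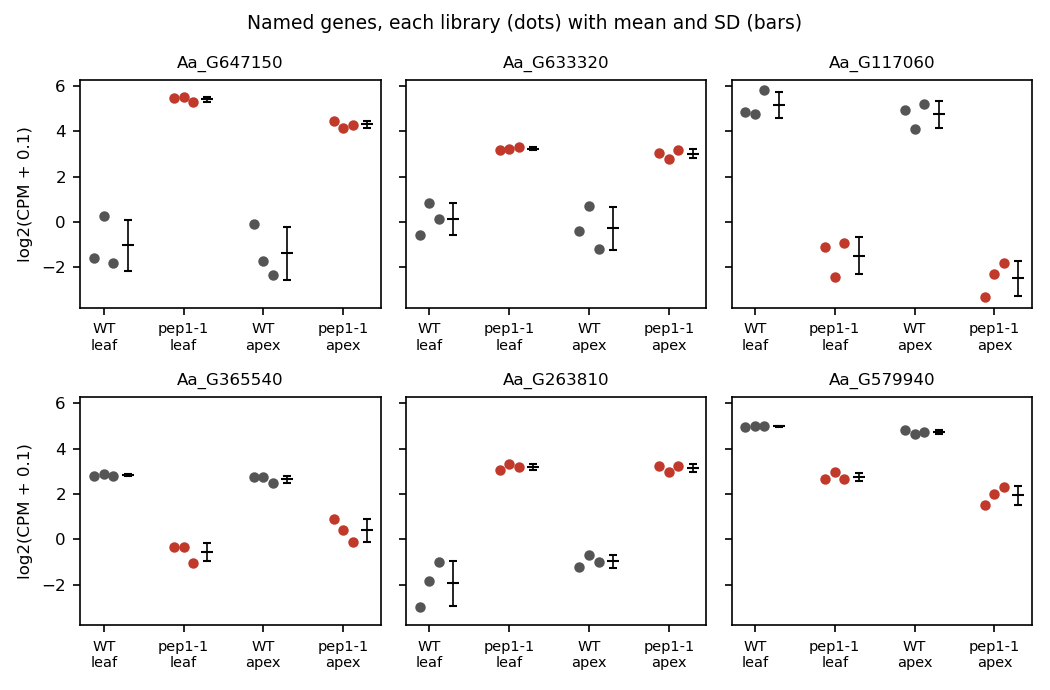
Levels of the 6 genes named in the genotype comparisons, as log2(CPM + 0.1), in each library (dots, grey for WT and red for pep1-1), with the mean and SD of 3 replicates beside them. CPM was scaled within leaf and within apex separately, so heights cannot be compared between the tissues. In every gene the 3 mutant libraries and the 3 WT libraries of a tissue do not overlap, which the rule required in the tissue where the gene was named.

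In the apex, 52 of 22157 genes passed the threshold, 34 higher and 18 lower in pep1-1. Of these, 43 changed at least 2-fold and 22 at least 4-fold. At an unadjusted p under 0.05 there were 2376 genes, against 1107.85 expected by chance. Replicates varied more in apex, with a common biological coefficient of variation of 15.1% against 10.2% in leaf. The spread of the apex genes over chromosomes had a permutation p of 0.377, and the p was under 0.05 in 2 of 17 alternatives. Each library moved the count: it was 15, 19 and 24 without WT apex replicates 1, 2 and 3, and 22, 140 and 31 without pep1-1 apex replicates 1, 2 and 3. It was 412 with DESeq2, 320 with all 12 libraries in one fit and 89 without the low-count filter.

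**Figure D2:**
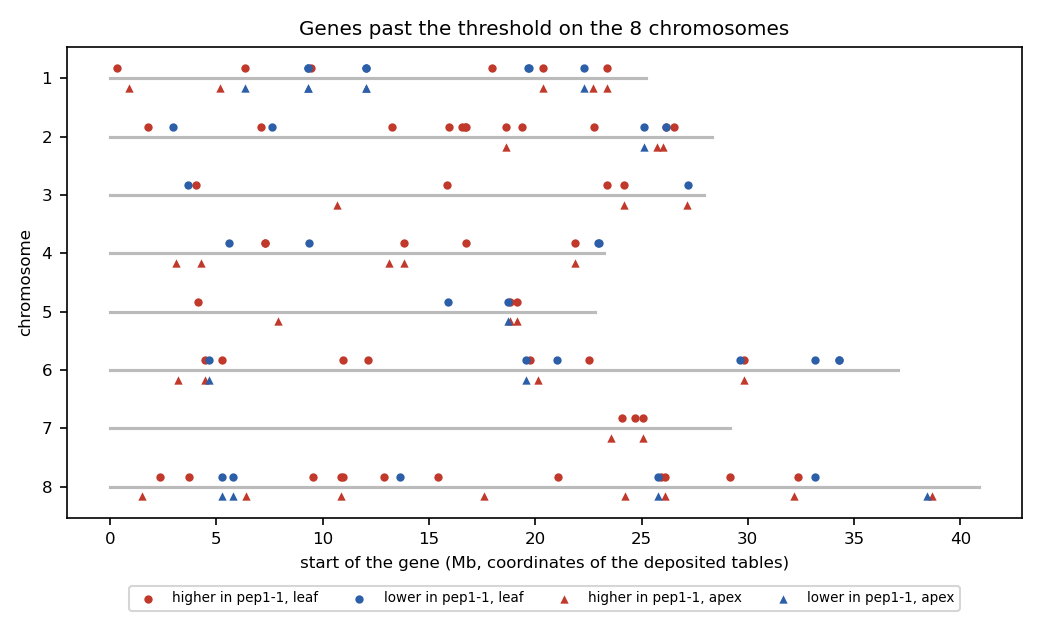
Start positions, in Mb, of the genes past the threshold on the 8 chromosomes, for leaf (circles) and apex (triangles), red where higher and blue where lower in pep1-1. Grey lines run to the end of the last annotated gene; genes on unplaced scaffolds, 12 in leaf and 5 in apex, are not drawn.

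Whether pep1-1 and WT differ in the same genes in both tissues was tested as an overlap. Only pep1-1 and Pajares plants were compared, so the mutation cannot be told apart from other differences between them. Of 21658 genes tested in both, 28 were past the threshold in leaf and in apex, all in the same direction, with 13 higher and 15 lower in pep1-1. Independent lists would share 0.0813 and 0.0290 genes (one-sided Fisher's exact p = 1.32e-26 and 1.54e-41). The 64 genes past the threshold in leaf alone all had the same sign in apex, where their median size was 0.75 on the log2 scale against 1.11 in leaf. The 21 genes past it in apex alone all had the same sign in leaf, with medians of 0.65 in leaf and 1.35 in apex. Larger medians in the tissue where the genes passed follow from how they were chosen. Log2 fold changes of the 2 tissues correlated across all genes tested in both (r = 0.551, rho = 0.388), and genes are not independent replicates. The shared count was 12 without WT apex replicate 1 and 15 without WT apex replicate 2, 124 with DESeq2 and 59 with all 12 libraries in one fit.

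**Figure D3:**
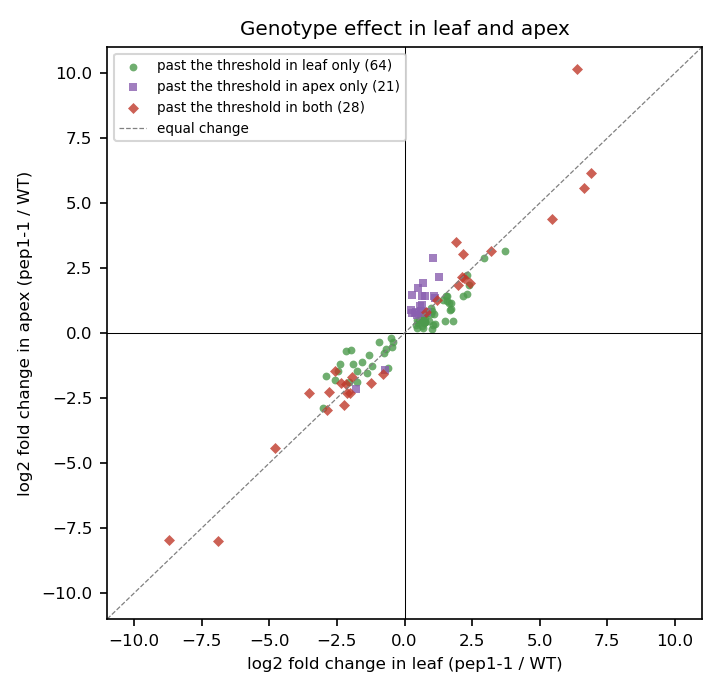
Log2 fold change of pep1-1 over WT in leaf (horizontal) and apex (vertical) for genes past the threshold in leaf only (64, circles), apex only (21, squares) or both (28, diamonds). The dashed line marks equal change, and every point lies in a quadrant where both tissues have the same sign.

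Whether the genotype effect differs between tissues was tested with the interaction term. No gene of 23517 passed in edgeR, where 991 had an unadjusted p under 0.05 against 1175.85 expected by chance. The smallest edgeR adjusted p was 0.190, for a gene on chromosome 4 (21856576 to 21859137) whose log2 fold change was 1.91 in leaf and 3.49 in apex. Among the 119 genes past the threshold in either tissue, 35 had an unadjusted interaction p under 0.05 and 13 passed in edgeR when adjusted over those genes alone, which is not independent evidence because they were chosen on the same libraries. DESeq2 called 7 genes, with that gene on chromosome 4 the strongest (DESeq2 adjusted p = 7.73e-07), and limma-voom called 0. In edgeR 1 gene passed without pep1-1 apex replicate 2. Simulated interactions of 2-fold were recovered in 52.2% of cases, and those of 1.5-fold in 10.8%, so smaller differences between tissues would mostly be missed. Recovery in these libraries may be lower, because simulated genes of one level shared one dispersion and many were changed at once.

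Apex and leaf were compared in WT to describe the tissues. Aa_G180310 on chromosome 7 (24939160 to 24941576) stood at 986 ± 192 CPM in apex and 7.03 ± 3.31 CPM in leaf, and Aa_G453790 on chromosome 6 (17539521 to 17545065) at 444 ± 80.7 and 3.73 ± 0.567 CPM (SD, n = 3 each). Aa_G804220 on chromosome 7 (4374059 to 4374713) was a leaf transcript, at 2211 ± 201 CPM in leaf and 1.34 ± 0.438 CPM in apex. Aa_G832170 on chromosome 6 (20638553 to 20639769) stood at 311 ± 19.9 CPM in leaf and 15.7 ± 5.83 CPM in apex. Their log2 fold changes, apex over leaf, were 7.11 (SE 0.34), 6.90 (SE 0.28), -10.67 (SE 0.26) and -4.32 (SE 0.30), with edgeR adjusted p from 3.99e-11 to 5.84e-08. Of 23517 genes, 15300 passed the threshold, 7554 higher in apex and 7746 higher in leaf. At least 2-fold differences were found for 6878 genes and at least 4-fold differences for 2660.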

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

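The test of transcripts left out of the comparisons was chosen after the data had been seen. When all transcripts were tested in leaf, 1 gene passed the threshold only through a transcript that the comparisons had not used. It lies on the scaffold scaff_73268_1 (12317 to 14943) and was lower in pep1-1 leaves, with a log2 change whose size was 1.86 and an edgeR adjusted p = 0.0473. The transcript used for that gene had a log2 fold change of -0.30 and an edgeR adjusted p = 0.259. In apex no gene was added in this way.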

How the results depend on the processing

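Testing all transcripts, the first transcript, and genes without overlapping models was chosen after the data had been seen; all 3 left each count of genes within 1.5 times. Across the counts of the 5 comparisons, 69 values stayed within 1.5 times and 27 did not. With the DESeq2 Wald test the counts were 322 in leaf, 412 in apex, 7 for the interaction and 124 shared. Without the low-count filter they were 157 in leaf and 89 in apex. One fit of all 12 libraries gave 320 in apex and 59 shared. An adjusted p under 0.01 left 34 in leaf, 17 in apex and 13 shared, and a 2-fold minimum left 6878 between the tissues, both by construction of a stricter threshold. Leaving out 1 library gave 39 to 445 in leaf, 15 to 140 in apex, 0 to 1 for the interaction and 12 to 32 shared. Genes past the threshold in 1 tissue alone had the same sign in the other for 92.1% to 100% of genes. The causes of the other shifts were not tested. Named genes kept their call in all 17 alternatives, none reversed, except Aa_G365540 in apex, whose call ended in 3. The 15 gene lists and their alternatives were not run, because identifiers are not paired with names.

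Deviations of same-numbered WT and mutant libraries correlated at 0.042, 0.20 and -0.090 in leaf and 0.31, -0.0065 and 0.28 in apex. Pairing was accepted only where every pair exceeded 0.1, so the numbers were not taken as pairs. Not every sample correlated best with its own number. In apex, however, replicates 1 and 3 deviated together, and WT and mutant libraries numbered 1 and 3 correlated at -0.29 and -0.30. Deviations were taken from the mean of 3 libraries, so a shared effect separating replicates 1 and 3 can leave replicate 2 uncorrelated. The rule therefore cannot exclude such an effect in apex. With the replicate number as a block the counts were 54 in leaf, 600 in apex, 0 for the interaction, 15423 between tissues and 38 shared. The permutation p of the apex spread over chromosomes was 0.00105 with the block and 0.0253 with DESeq2.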

Other observations

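Of the tests in this part, library depth and the splits of the tissue libraries were set before their results were seen; all others were chosen after their results or the counts they concern had been seen. A group of genes was close to absent in one genotype. In both tissues 7 genes differed at least 16-fold in the same direction, 3 of them low in pep1-1 and 4 low in WT. One on chromosome 6 (19562629 to 19564983) had 250 reads over the WT libraries and 0 over the 6 mutant libraries. Another on chromosome 7 (25050637 to 25054110) had 737 reads in the mutant and 3 in WT.

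Other splits of the same libraries gave fewer genes. The real leaf, apex and WT tissue splits gave 95, 52 and 15300 genes, and the highest other split gave 3, 0 and 0. Only 1 of 10 splits reached the real count in each, and 10 splits are too few for a share under 0.05. Every other split mixes genotypes or tissues within a group, so a real difference raises its spread and lowers its count. For the tissues the common biological coefficient of variation was 12.9% in the real split and 34.7% to 35.5% in the others. For the interaction the real count was 0, which any split reaches (30 of 30 drawn, highest other 1), so the splits say nothing about it. Of 200 combinations of leaf and apex splits, 1 reached the 28 shared genes, the real one, and the highest other gave 0. The other apex splits held 0 genes and the other leaf splits at most 3, too few to share as many, so these combinations add nothing to the splits of each tissue, and the overlap rests on Fisher's exact test.

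On a score of 1394 apex genes minus 1107 leaf genes, mutant groups had the higher means, -0.65 ± 0.16 in pep1-1 leaf and -0.99 ± 0.29 in WT leaf (exact two-sided p = 0.3, n = 3, with WT leaf replicate 1 at -0.66 among the mutants), and 5.58 ± 0.26 and 5.20 ± 0.17 in apex (exact p = 0.1, n = 3, the smallest possible; difference 0.24 in place of 0.38 without pep1-1 apex replicate 3). The genes of the score differed by at least 2 on the log2 scale between the tissues, over all 12 libraries of both genotypes. In leaf the median log2 change in pep1-1 was 0.25 for the apex genes and -0.045 for the leaf genes. In apex these medians were 0.17 and -0.12. Library depth is argued against, since thinning every library to one total kept at least 92.3% of the score difference in each tissue. Genes 4- to 16-fold higher in apex had a median log2 change of 0.22 in mutant leaves, which an added apex share of 3.11% would give; that share would need 0.88 (0.78 to 0.99) in 50 genes at least 16-fold higher in apex with at least 1 CPM in leaf, which had 0.47 (0.26 to 0.59). Genes 4- to 16-fold higher in leaf had -0.21 in mutant apices, which a removed leaf share of 2.47% would give. That share would need -0.89 (-1.55 to -0.63) in 24 genes at least 16-fold higher in leaf with at least 1 CPM in apex. These 24 genes had -0.33 (-0.56 to -0.10). In both tissues the observed median was smaller in size than the mixture would need. Values in brackets are 95% intervals from resampling genes. They leave out the spread between libraries, and genes are not independent replicates. Mixed tissue as the whole cause is therefore not decided in either tissue, and a smaller share stays open. A genotype effect may remain (one-sided permutation p = 0.0125 over 400 assignments, in a direction chosen from the data), and a shift in developmental stage or cell makeup was not tested.

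Genes past the threshold in either tissue lay next to each other more often than random genes. Among 119 genes, 6 pairs lay within 10 kb, where random draws gave 0.844 on average (permutation p = 0.00040), and all 6 pairs changed in one direction, 5 lower and 1 higher in pep1-1. They lie on chromosome 1 (9309270 to 9313861, 12026933 to 12030136 and 19674025 to 19688530), chromosome 4 (7269789 to 7272493), chromosome 6 (34312433 to 34313569) and scaff_73268_1 (8857 to 11571). The annotated spans of 0 pairs overlapped, with gaps from 73 to 7765 bp, so reads in overlapping spans are argued against for these pairs. Only 289 of 35465 genes overlap another model, so few overlapping pairs could occur. This count says nothing about reads shared between neighbours in other ways. Reads shared between near-identical neighbours may contribute and were not tested; with each library left out the permutation p was at most 0.0142, with 23 pairs among 464 genes without WT leaf replicate 1, 3 pairs without pep1-1 leaf replicate 1, 3 without pep1-1 leaf replicate 3 and 9 without pep1-1 apex replicate 2.

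The 7 near-absent genes kept a median of 0.196% of their pooled reads in each library of the low genotype, and reads carried over between pooled libraries are a candidate source. One uniform carry-over would set that share as a floor for every gene, whereas 35 of the 100 genes with the largest tissue difference lay under 0.5 of it (lowest 0.00436%, median of the 100 genes 0.235%), which argues against it as the whole source. The gene set was redefined after its first result, and what part of a set lies under the floor follows from the fold change that defines it: 29 of 30 genes at an absolute log2 fold change of 8, and 35 of 188 at 4. Low transcription in the low genotype stays open and was not tested.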
